A study of Marchantia polymorpha with 4 samples.

How the data were processed

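Transcript levels were measured in thallus of the liverwort *Marchantia polymorpha*, accession Tak-1 (Takaragaike-1), with 2-colour Agilent oligonucleotide arrays. Per the labels, plants had grown in soil for 4 weeks, and a lobe was crushed on the plants to be wounded. Tissue was frozen 4 h later. The 3 tissues were thallus of intact plants, the crushed lobes, and the undamaged lobes of the wounded plants, called systemic tissue here. Each RNA sample came from a pool of 10 plants and was DNase-treated, per the labels, and 200 ng was amplified with T7 RNA polymerase and labelled with Cy3 or Cy5. There were 2 biological replicates per comparison. Each of the 4 arrays held a treated sample against an intact sample. In replicate 1 of both comparisons the treated RNA carried Cy5, and in replicate 2 it carried Cy3, so that a dye effect cancels in the mean of a comparison. All 4 arrays lay on 1 slide and were scanned in 1 scan, so neither could be tested as a batch. The names of the deposited files show that same-numbered arrays of the 2 comparisons shared their intact RNA.

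The deposited scanner files were made with Agilent Feature Extraction 10.7.3.1 and its GE2_107_Sep09 protocol on array design 084032, per the file headers. They give mean foreground and median local background intensity of each spot for both dyes, per the file headers, and a log10 ratio of red over green computed by the scanner software after its own background correction and dye normalization. The authors also deposited a table of processed values per spot, used here as an alternative and read as log2 ratios. Its column medians were -0.02, -0.03, 0 and 0 for locally wounded replicates 1 and 2 and systemic replicates 1 and 2. Over all gene spots its columns correlated with the scanner's red over green ratio at 0.894, -0.826, 0.737 and -0.735, which settles the direction as treated over intact. Regressed on the scanner's log2 ratio over spots well above background, the slopes were 0.842, -0.770, 0.751 and -0.761. The column means lay between -4.2e-05 and 6.19e-06, so each array was centred on its mean. The log base and the normalization method of that table are not given in the sources used here, so its scale stays inferred from the slopes.

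Intensities were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, with files read by data.table (1.17.8). The 1319 control spots per array were then removed, and each array was normalized by loess (span 0.3, 4 iterations) over its 60103 gene spots. Spots marked as outliers by the scanner software (130, 75, 67 and 68 per array) were left out, and 0 spots were saturated. Log2 ratios were turned to treated over intact, and spots were averaged per probe and probes per gene model. A probe was tested when at least a share of 0.5 of its spots was well above background in every channel that held the RNA of at least 1 of the 3 tissues, which 20982 of 40422 probes met. This left 11595 of 20700 gene models, from 10954 loci, and 9213 of them had several probes. The array numbered 61422 spots in all, and spots absent from that numbering were not analysed here. Gene models keep the identifiers of the array design. Their functions come from the description of the best Arabidopsis match in the scanner files, which 9528 tested models have and 8354 of them with a named function. The descriptions of 2067 tested models are empty. Of the identifiers, 0 matched the reference gene table (assembly MpTak2_v7.1), so no genome positions are given. A sequence common to several gene models was carried by 250 probes, which cannot tell those models apart.

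Both comparisons and their difference were tested with limma (lmFit and eBayes) in a fit to all 4 arrays, with 2 residual degrees of freedom and a prior of 3.35. P-values were adjusted by Benjamini-Hochberg, and a gene model was called changed at an adjusted p under 0.05. Every adjusted p given for a gene model comes from limma's moderated test, and values are mean log2 ratios ± SD over 2 arrays. With 2 arrays per comparison, the number of arrays limits the precision. The median standard error was 0.144 for each comparison and 0.204 for their difference. Because same-numbered arrays shared intact RNA and dye orientation, a fit with the replicate number as a block was also made, with 1 residual degree of freedom. Deviations of same-numbered arrays from their group means correlated at r = 0.349 across genes, against 0.343 (0.275 to 0.400) in 100 simulations of unchanged groups that share intact RNA. Where a channel was not well above background on any array of a tissue, a fold is given as a bound: the other tissue's mean after loess and Aquantile over the higher of the probe's own signal and the lowest signal of probes well above background.

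Gene lists were fixed as patterns on the description text before the data were examined, among them markers of oil body cells and of antheridia and 2 lists on RNA quality. For each list the text gives the members called over all genes and those adjusted over the list alone. The 34 lists with at least 5 tested members were tested with limma's camera (preset correlation 0.01), adjusted over all lists and comparisons. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 lists passed, against 38 list and comparison pairs with the preset value at an adjusted p under 0.05 and 18 by fry. The estimated version refers its statistic to the 2 residual degrees of freedom, so few lists can pass. Correlation among members is not always the reason. For local peroxidases it was estimated at -0.00603, below the preset value, yet the camera p rose from 1.35e-19 to 0.00517. For local glutathione transferases it was -0.00952, and the camera p rose from 8.47e-08 to 0.0265. The rule for named genes was fixed at the same time. It takes, per comparison, the 8 largest changes in each direction among called gene models with the same sign on both arrays and a description that names a function. Where fewer than 4 pass, the 4 with the smallest p in each direction are given as not past the test. It adds the 3 members of each list with the smallest p.

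The pipeline was tested on simulated data. In a simulated local comparison of 11595 genes, 0 of 67 genes changed 1.5-fold, 16 of 67 changed 2-fold and 60 of 66 changed 4-fold were called, with 8 false calls. In the simulated difference 0 of 67, 0 of 67 and 28 of 66 were called, with 1 false call. A list of 23 members shifted by 0.5 was found in the simulated local comparison, with 0 others. Genes and arrays were drawn as independent, and far fewer genes were changed than were called in the data. These runs thus do not show how many sets are falsely called when members correlate or arrays share intact RNA. Alternatives covered the background correction, the normalization, the authors' deposited values, the filter, the averaging of probes, the variance model, the replicate block and leaving out each array.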

Results

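The data are 4 two-colour arrays that set *Marchantia* thallus from wounded plants against thallus from intact plants, 4 h after a lobe had been crushed. Of these, 2 arrays hold the crushed (locally wounded) lobes and 2 hold undamaged lobes of the wounded plants (systemic tissue). Every treated and intact RNA was a pool of 10 plants, and the 2 replicates of each comparison were biological. The share of gene spots well above background was 47.6% and 48.4% for locally wounded tissue in replicates 1 and 2, 54.0% and 49.3% for systemic tissue, and between 46.4% and 56.5% for intact tissue. The question was which transcripts respond to wounding at the site of damage and which respond at a distance. Values are mean log2 ratios over intact plants ± SD (n = 2 arrays), and gene names are those of the best Arabidopsis match of each gene model.

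Locally wounded tissue differed broadly from intact thallus. Gene lists of heat shock proteins, glutathione transferases, WRKY factors and oxylipin synthesis shifted upward as sets, class III peroxidases mostly fell, and the cell wall and photosynthesis lists shifted downward with a minority of their members called. These set shifts rest on camera with a preset correlation. With an estimated correlation, where the 2 residual degrees of freedom leave little power, 0 of 34 lists passed (lowest adjusted p = 0.274). By fry 10 lists passed, of which 7 were among the 18 that passed camera. Of the lists just named, peroxidases and glutathione transferases (fry adjusted p = 0.0133 for both), WRKY factors (0.0344) and the cell wall (0.0441) passed by fry. Heat shock proteins (0.0553), oxylipin synthesis (0.0653) and photosynthesis (0.248) did not. Of 11595 gene models tested, 3057 (26.4%) were called, 1794 higher and 1263 lower, and 926 of the higher and 403 of the lower ones changed at least 2-fold. All 3057 had the same sign on both arrays, which a call in this fit requires, so it is no separate sign of agreement. The largest increase was that of Mapoly0190s0002.3 at 5.25 ± 0.32 (38.0-fold, adjusted p = 0.00035), matched to VEP1, also named AWI31, an enone reductase induced by wounding in Arabidopsis. A second model of that locus, Mapoly0190s0002.1, rose by 5.08 ± 0.20. Mapoly0166s0010.1, matched to the AP2/ERF transcription factor Rap2.6L, rose by 5.05 ± 0.51, and Mapoly0097s0082.1, matched to the OPDA reductase OPR1, rose by 4.84 ± 1.12. The co-chaperone BAG6 (Mapoly0035s0113.1) rose by 4.55 ± 0.14 and the calcium pump ECA3 (Mapoly0040s0031.1) by 4.54 on both arrays. Mapoly0010s0142.1, matched to the small heat shock protein HSP17.6A, rose by 4.43 ± 0.61. Mapoly0033s0061.1, matched to CYP90A1, which in Arabidopsis acts in brassinosteroid synthesis, rose by 4.34 ± 1.43 (adjusted p = 0.0048).

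**Figure D1:**
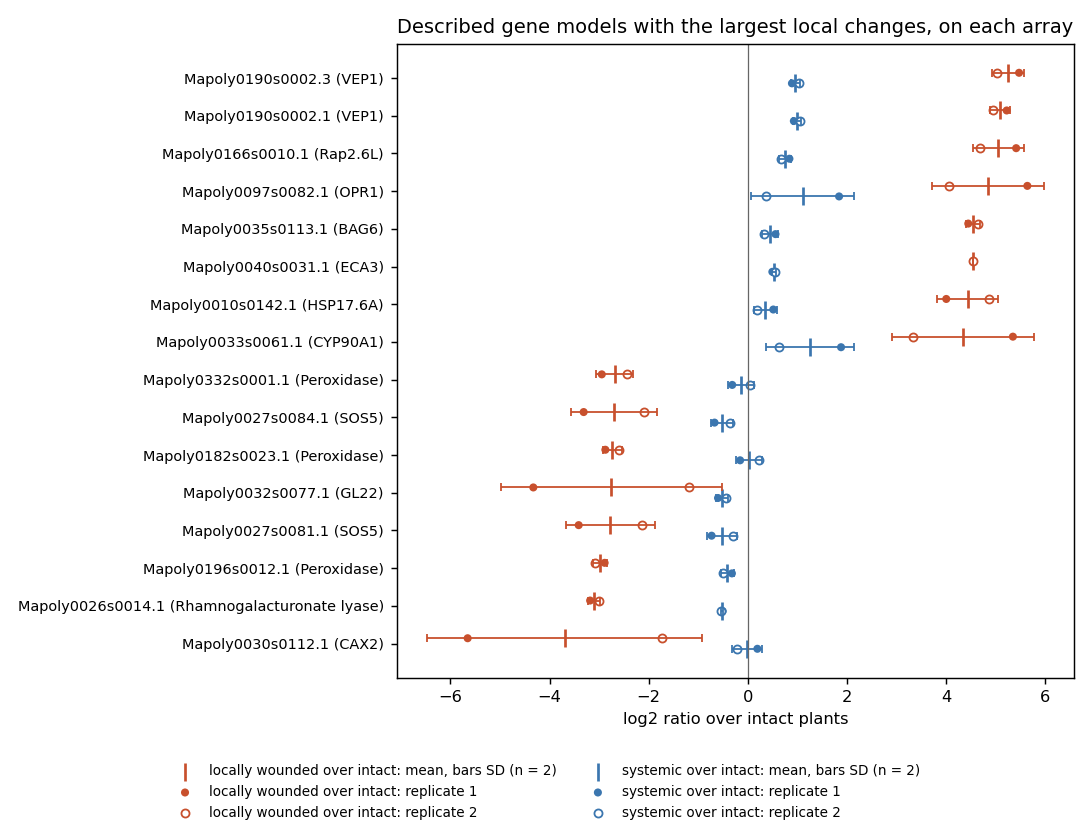
Log2 ratio over intact plants of the 16 gene models with the largest local changes among those with a described function, for each array (points), with the mean and SD of the 2 arrays of locally wounded (red) and systemic tissue (blue). Local means reach 5.25 and -3.69, while the systemic means of the same gene models lie between -0.52 and 1.25.

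Among called gene models with a described function, the 8 largest decreases include 3 peroxidases. Mapoly0030s0112.1, matched to the vacuolar cation exchanger CAX2, fell by 3.69 with the widest spread of these genes (SD 2.77, adjusted p = 0.0319). A rhamnogalacturonate lyase (Mapoly0026s0014.1), an enzyme that cleaves pectin, changed by -3.10 ± 0.12. A pair of fasciclin-like arabinogalactan proteins matched to SOS5 changed by -2.78 ± 0.90 (Mapoly0027s0081.1) and -2.70 ± 0.86 (Mapoly0027s0084.1). Mapoly0032s0077.1, a germin-like protein, changed by -2.76 ± 2.22 (adjusted p = 0.0392). Without either systemic array, which enters through the common estimate of the spread, its adjusted p was 0.0568. The peroxidases Mapoly0182s0023.1 and Mapoly0332s0001.1 changed by -2.74 ± 0.19 and -2.69 ± 0.37. A further peroxidase, Mapoly0196s0012.1, had a log2 ratio of -2.98 ± 0.13 but was not well above background in wounded tissue. Its bound, 7.91-fold lower there, was set by its own signal and equals that ratio, so it leaves no margin.

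The lists of oxylipin synthesis and of several transcription factor families shifted upward. In the oxylipin list, which covers the plastid and peroxisome steps that make OPDA and jasmonate-type compounds, 12 of 23 gene models rose and 2 fell, the same numbers as adjusted over the list alone (median 0.70, camera adjusted p = 0.0043, adjusted p = 0.709 with an estimated correlation). Beside OPR1 these include the acyl-CoA oxidases ACX1 (Mapoly0169s0009.1) at 1.59 ± 0.07 and ACX2 (Mapoly0014s0189.1) at 1.34 ± 0.19. All 12 WRKY factors had positive ratios, and 10 rose and 0 fell both over all genes and adjusted over the list alone (median 1.48, camera adjusted p = 8.3e-07, adjusted p = 0.709 with an estimated correlation). WRKY42 (Mapoly0039s0030.1) rose by 3.09 ± 0.36, WRKY20 (Mapoly0008s0159.1) by 2.66 ± 0.09 and WRKY35 (Mapoly0051s0057.1) by 2.04 ± 0.19. Of 15 gene models in the AP2/ERF list 6 rose and 0 fell, with the same counts adjusted over the list alone (median 0.28, camera adjusted p = 0.0358, adjusted p = 0.709 with an estimated correlation). The pattern behind that list also took in 9 proteins of other kinds, such as translation release factors and B3 factors. Without them, an alternative added after the values were seen (as for the 3 lists treated alike below), 4 of 6 rose and 0 fell, also adjusted over the list alone (median 2.11, camera adjusted p = 0.00393, adjusted p = 0.656 with an estimated correlation). ERF-1 (Mapoly0068s0088.1) rose by 2.72 ± 0.55 and ERF4 (Mapoly0001s0341.1) by 1.98 ± 0.03.

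In the NAC list 4 of 7 factors rose and 0 fell, against 4 and 1 adjusted over the list alone (median 1.01, camera adjusted p = 0.0439, adjusted p = 0.709 with an estimated correlation), and with the replicate block its camera adjusted p was 0.0662. RD26 (Mapoly0035s0049.1), a factor induced by dehydration in Arabidopsis, rose by 2.12 ± 0.44, and NAC028 was the match of Mapoly0020s0051.1 at 1.94 ± 0.04. Among 21 MYB factors 8 rose and 1 fell, also adjusted over the list alone (median 0.31, camera adjusted p = 0.0441, adjusted p = 0.725 with an estimated correlation). MYB84 (Mapoly0874s0001.1) rose by 1.60 ± 0.50 and MYB6 (Mapoly0073s0038.1) by 1.31 ± 0.04. For the MYB list the adjusted p was 0.257 without locally wounded replicate 1.

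The lists of glutathione transferases, heat shock proteins, dehydration and proteasome genes shifted upward. Of 27 glutathione transferases, which conjugate reactive compounds to glutathione, 15 rose and 1 fell, against 16 and 1 adjusted over the list alone (median 0.82, camera adjusted p = 1.23e-06, adjusted p = 0.541 with an estimated correlation). GSTF10 (Mapoly1812s0001.1) rose by 4.26 ± 0.33, GSTF9 (Mapoly0177s0013.1) by 3.80 ± 0.22 and GSTU8 (Mapoly0031s0032.1) by 3.45 ± 0.05. Among 74 heat shock proteins 34 rose and 2 fell, also adjusted over the list alone (median 0.34, camera adjusted p = 3.59e-06, adjusted p = 0.709 with an estimated correlation). A second HSP17.6A match (Mapoly0010s0143.1) rose by 4.09 ± 0.51 and the plastid chaperone cpHsc70-2 (Mapoly0110s0006.1) by 2.99 ± 0.34. The abscisic acid and dehydration list had 49 higher and 14 lower gene models of 158, against 51 and 15 adjusted over the list alone (camera adjusted p = 0.0158, adjusted p = 0.725 with an estimated correlation). Its median of 0.29 turned to -0.01 under median centring, where the median of all genes was -0.25. Its pattern also caught 78 enzymes of pyruvate, pyridoxal, pyrimidine and pyrophosphate metabolism. Without those, 38 of 80 rose and 7 fell, against 41 and 7 adjusted over the list alone (median 0.91, camera adjusted p = 1.12e-05, adjusted p = 0.656 with an estimated correlation). The dehydrin ERD10 (Mapoly0056s0073.1) rose by 2.82 ± 0.19 and a protein phosphatase 2C (Mapoly0035s0123.1) by 2.36 ± 0.09. The list as fixed had an adjusted p of 0.157 without locally wounded replicate 2. Of 37 proteasome and autophagy gene models 6 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00517, adjusted p = 0.710 with an estimated correlation). The median of that list, 0.20, turned to -0.12 under median centring, where that of all genes was -0.25. The proteasome activator PA200 (Mapoly0071s0029.1) was among the members that rose, at 1.26 ± 0.09.

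The lists of phenylpropanoid, shikimate, sugar transport and oil body genes also shifted upward. Of 82 phenylpropanoid and flavonoid gene models 30 rose and 10 fell, against 37 and 16 adjusted over the list alone (median 0.38, camera adjusted p = 0.0261, adjusted p = 0.725 with an estimated correlation). Dirigent-like proteins, which guide the coupling of phenolic radicals, rose by 3.86 ± 0.15 (Mapoly0117s0014.1) and 2.54 ± 0.31 (Mapoly0135s0043.1), and the acyltransferase HCT (Mapoly0003s0198.1) rose by 2.72 ± 0.14. In the shikimate and aromatic amino acid list, which supplies their precursors, 8 of 18 rose and 1 fell, against 11 and 1 adjusted over the list alone (median 0.47, camera adjusted p = 0.0209, adjusted p = 0.710 with an estimated correlation). A prephenate dehydrogenase (Mapoly0031s0116.1) rose by 2.37 ± 0.31 and chorismate synthase (Mapoly0007s0052.1) by 1.26 ± 0.45. The shikimate list had an adjusted p of 0.0511 without locally wounded replicate 1. Among 28 sugar transport and sucrose gene models 8 rose and 1 fell, also adjusted over the list alone (median 0.29, camera adjusted p = 0.0158, adjusted p = 0.710 with an estimated correlation). Sucrose synthase SUS3 (Mapoly0122s0057.1) rose by 2.70 ± 0.45 and the sugar transporter STP7 (Mapoly0175s0014.1) by 2.45 ± 0.28. The list of oil body cell markers had 8 higher and 1 lower gene models of 19, against 10 and 2 adjusted over the list alone (median 0.53, camera adjusted p = 0.0127, adjusted p = 0.709 with an estimated correlation). Its strongest members were ABC transporters of a family known from many cell types, ABCG14 (Mapoly0097s0053.1) at 4.04 ± 0.38, PDR11 (Mapoly0040s0080.1) at 3.77 ± 0.20 and PDR8 (Mapoly0087s0041.1) at 2.77 ± 0.37, while oleosin OLE1 (Mapoly0048s0029.1), a coat protein of lipid droplets, rose by 1.21 ± 0.08.

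Class III peroxidases, secreted enzymes that oxidise phenolics and cross-link wall polymers, formed the strongest downward shift. Of 136 gene models 89 fell and 9 rose, against 96 and 10 adjusted over the list alone (median -1.0, camera adjusted p = 1.38e-17, adjusted p = 0.274 with an estimated correlation). The list took in 3 proteins that are not class III peroxidases, and without them 89 of 133 fell and 8 rose, against 96 and 9 adjusted over the list alone (median -1.04, camera adjusted p = 1.43e-18, adjusted p = 0.269 with an estimated correlation). Laccase LAC11 (Mapoly0049s0002.1), the only tested member of the laccase list and another phenol oxidase, changed by -1.38 ± 0.25 (adjusted p = 0.00292). In the cell wall list 40 of 105 gene models fell and 5 rose, against 44 and 7 adjusted over the list alone (median -0.47, camera adjusted p = 2.15e-06, adjusted p = 0.709 with an estimated correlation). The xyloglucan-modifying enzymes went both ways, with XTH16 (Mapoly0089s0005.1) at -1.89 ± 0.10 and XTH5 (Mapoly0094s0049.1) at 2.34 ± 0.13, and arabinogalactan protein AGP20 (Mapoly0079s0002.1) rose by 2.63 ± 0.02. Of 134 photosynthesis gene models 27 fell and 7 rose, against 41 and 8 adjusted over the list alone (median -0.37, camera adjusted p = 5.56e-05, adjusted p = 0.710 with an estimated correlation). The stress-induced light-harvesting relative ELIP2 (Mapoly0047s0106.1) rose by 3.18 ± 0.20, and antenna proteins matched to LHCB2 went in opposite directions, with Mapoly0068s0087.1 at 4.11 ± 0.59 and Mapoly0139s0012.1 at -0.99 ± 0.33.

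Chlorophyll synthesis had 4 lower and 0 higher gene models of 10, also adjusted over the list alone (median -0.36, camera adjusted p = 0.0225, adjusted p = 0.710 with an estimated correlation). Uroporphyrinogen decarboxylase HEME2 (Mapoly0103s0078.1) changed by -1.31 ± 0.40 and magnesium chelatase subunit CHLI2 (Mapoly0040s0099.1) by -1.0 ± 0.50. Of 31 aquaporin and water transport gene models 15 fell and 1 rose, against 15 and 2 adjusted over the list alone (median -0.57, camera adjusted p = 0.00345, adjusted p = 0.710 with an estimated correlation). The member that rose, Mapoly0011s0006.2 at 1.72 ± 0.18, is an ankyrin repeat protein that bears the symbol TIP1. Without this and 4 other gene models of other kinds, 15 of 26 aquaporins fell and 0 rose, against 16 and 0 adjusted over the list alone (median -0.63, camera adjusted p = 3.04e-05, adjusted p = 0.656 with an estimated correlation). The tonoplast channel TIP2 (Mapoly0005s0187.1) changed by -0.81 ± 0.02 and the plasma membrane channel PIP1B (Mapoly0042s0022.1) by -0.88 ± 0.08. Without locally wounded replicate 1 the adjusted p of the chlorophyll list was 0.0746, and CHLI2, TIP2 and PIP1B had adjusted p-values of 0.101, 0.0585 and 0.0618.

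**Figure D2:**
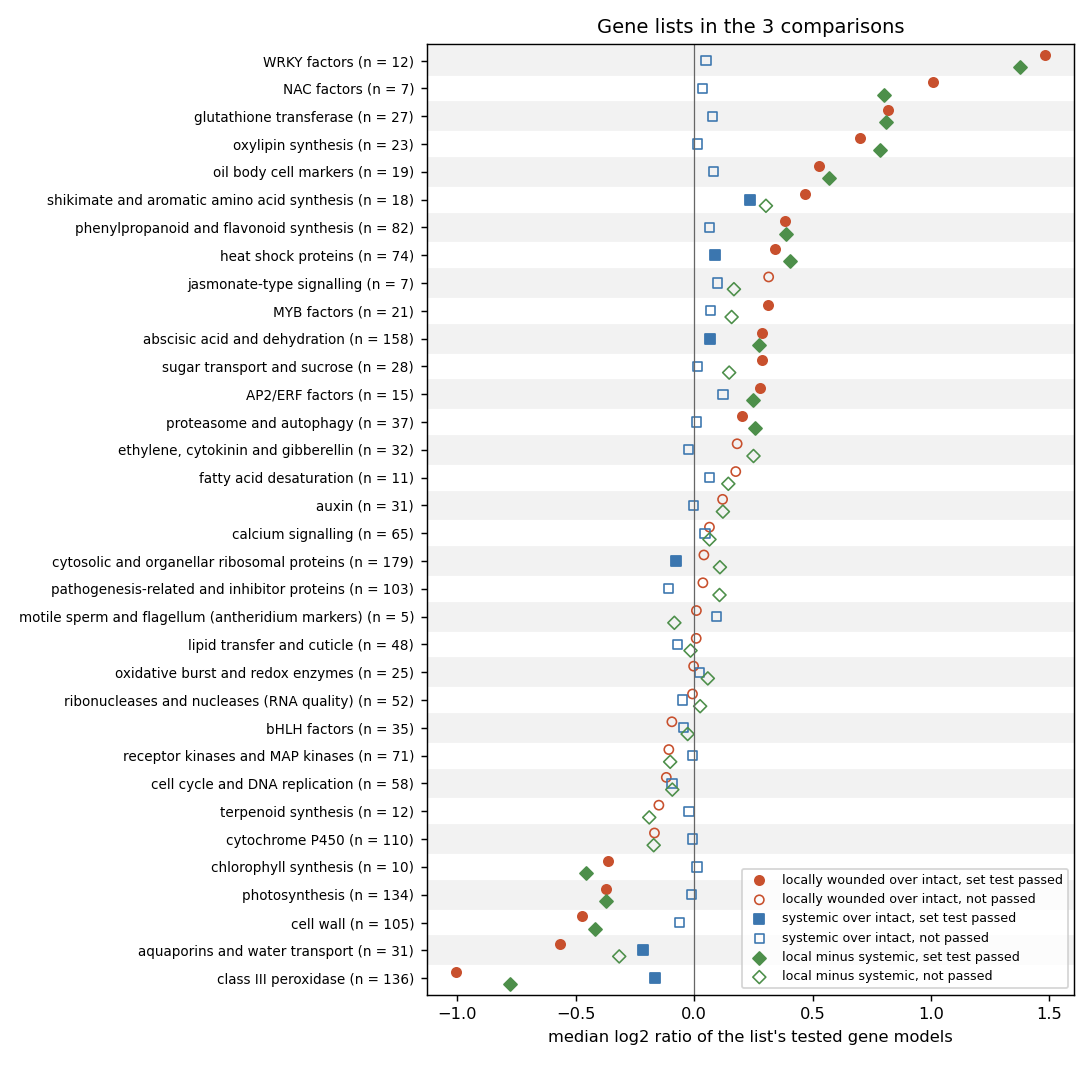
Median log2 ratio of the gene lists in locally wounded and systemic tissue over intact plants, and in local minus systemic, with the number of members tested. Filled symbols mark lists that passed the set test (camera with a preset correlation), and open symbols those that did not. The local medians run from -1.0 for class III peroxidases to 1.48 for WRKY factors, and 0 members were called in systemic tissue.

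The remaining lists changed in both directions or in few members, and none passed the set test by camera (adjusted p from 0.123 to 0.909). By fry, jasmonate-type signalling (adjusted p = 0.0268), fatty acid desaturation (0.0235) and the list of ethylene, cytokinin and gibberellin (0.0391) did pass. Of 110 cytochrome P450 gene models 15 rose and 18 fell (15 and 26 adjusted over the list alone). In the calcium signalling list 20 of 65 rose and 12 fell (22 and 15 adjusted over the list alone), with the EF-hand protein MSS3 (Mapoly0045s0017.1) at 3.35 ± 0.32. Receptor and MAP kinases had 15 higher and 19 lower of 71 (16 and 22 adjusted over the list alone), with the match of the flagellin receptor FLS2 (Mapoly0090s0078.1) at -2.0 ± 0.37. Of 35 bHLH factors 9 rose and 4 fell (9 and 5 adjusted over the list alone), and TT8 (Mapoly0028s0062.1), a regulator of flavonoid genes in Arabidopsis, rose by 3.62 ± 0.12. Pathogenesis-related and inhibitor proteins had 15 higher and 12 lower of 103, also adjusted over the list alone, with chitinase CHIA (Mapoly0118s0041.1) at 1.82 ± 0.17 and PR5 (Mapoly0033s0148.1) at -1.16 ± 0.02. The jasmonate-type signalling list had 2 higher and 0 lower of 7 (3 and 0 adjusted over the list alone), the repressors JAZ1 (Mapoly0097s0021.1) at 1.46 ± 0.21 and TIFY8 (Mapoly0079s0053.1) at 1.36 ± 0.06. Auxin genes had 8 higher and 5 lower of 31, also adjusted over the list alone, with the auxin-conjugating enzyme GH3.2 (Mapoly0053s0073.1) at 2.77 ± 0.80 and a SAUR protein (Mapoly0060s0079.1) at -2.25 ± 0.45. Ethylene, cytokinin and gibberellin genes had 7 higher and 0 lower of 32, and redox enzymes 7 higher and 1 lower of 25, in both cases also adjusted over the list alone.

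Fatty acid desaturases had 3 higher and 0 lower of 11 (4 and 2 adjusted over the list alone), and terpenoid synthesis 1 higher and 0 lower of 12, also adjusted over the list alone. Lipid transfer and cuticle genes had 6 higher and 10 lower of 48, also adjusted over the list alone. Among 179 ribosomal proteins 2 rose and 16 fell (1 and 4 adjusted over the list alone), and among 58 cell cycle genes 4 rose and 7 fell (4 and 6 adjusted over the list alone). Of 52 ribonucleases and nucleases, a list on RNA quality, 5 rose and 5 fell (3 and 3 adjusted over the list alone), among them the secreted ribonuclease RNS1 (Mapoly0015s0142.1) at 2.33 ± 0.92. The adjusted p of RNS1 was 0.0624 without locally wounded replicate 1. Markers of motile sperm, which would come from antheridia, had 0 higher and 1 lower of 5, also adjusted over the list alone, and 0 gene models on the array were organelle-encoded by their description.

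At an unadjusted p under 0.05 there were 4734 local changes, where 580 would come by chance. Median centring in place of loess moved the median of all genes to -0.25, called 1047 gene models (482 higher and 565 lower) and kept 79 of the 108 named local calls, and the authors' deposited table gave 1521 higher and 1699 lower against 1794 and 1263. Without locally wounded replicate 1 there were 1536 calls and without replicate 2 there were 2194.

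In systemic tissue the ratios were small. The SD of log2 ratios over tested genes was 0.305 and 0.361 on the systemic arrays, against 0.824 and 0.745 on the local arrays. With limma 0 gene models passed the test (smallest adjusted p = 0.559), while 875 had an unadjusted p under 0.05, 376 of them higher and 499 lower, where 580 would come by chance. With the replicate block the count was also 0, with 1549 at an unadjusted p under 0.05. Values with the smallest p on the higher side, none past the test, were those of the dirigent-like protein Mapoly0117s0014.1 at 1.51 ± 0.15, of the small membrane protein RCI2A (Mapoly0002s0223.1), induced by cold and salt in Arabidopsis, at 1.15 ± 0.12, of the temperature-induced lipocalin TIL (Mapoly0161s0027.1) at 1.01 ± 0.02 and of STP7 (Mapoly0050s0068.1) at 0.91 ± 0.13. Each of them was called higher in locally wounded tissue, at 3.86 ± 0.15, 1.38 ± 0.05, 3.97 ± 0.02 and 0.86 ± 0.02 in the same order. On the lower side, also not past the test, stood malate synthase (Mapoly0154s0035.1), an enzyme of the glyoxylate cycle, at -1.83 ± 0.68, a cupin (Mapoly0193s0021.1) at -1.18 ± 0.05, the plasma membrane proton pump AHA11 (Mapoly0006s0247.3) at -1.10 ± 0.30 and a methylenetetrahydrofolate reductase family member (Mapoly0001s0130.1) at -0.95 ± 0.16. Their local values were -1.28 ± 0.46, 0.68 ± 0.26, 0.41 ± 0.13 and 1.16 ± 0.07, of which that of AHA11 did not pass the test (adjusted p = 0.104).

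By camera with a preset correlation, some lists shifted as sets in systemic tissue although 0 of their members were called, over all genes or adjusted over the list alone. Of these lists as fixed, only class III peroxidases also passed by fry (adjusted p = 0.0200). Fry adjusted p-values were 0.327 for aquaporins, 0.482 for ribosomal proteins, 0.280 for shikimate, 0.523 for heat shock proteins and 0.704 for abscisic acid and dehydration. Class III peroxidases were lower (median -0.17, camera adjusted p = 3.18e-07, adjusted p = 0.446 with an estimated correlation), with Mapoly1623s0002.1 at -0.65 ± 0.12 and Mapoly0004s0139.1 at -0.67 ± 0.31. Aquaporins were lower (median -0.22, camera adjusted p = 0.00345, adjusted p = 0.710 with an estimated correlation), with the tonoplast channel TIP2;1 as the match of Mapoly0223s0005.1 at -0.66 ± 0.12. Ribosomal proteins were lower (median -0.08, camera adjusted p = 0.0186, adjusted p = 0.725 with an estimated correlation), with RPL16 (Mapoly0118s0046.1) at -0.75 ± 0.40. The shikimate list was higher (median 0.23, camera adjusted p = 0.0182, adjusted p = 0.710 with an estimated correlation), with dehydroquinate synthase (Mapoly0031s0094.1) at 0.54 ± 0.01 and anthranilate synthase ASB1 (Mapoly0037s0136.1) at 0.85 ± 0.34. Heat shock proteins were higher (median 0.09, camera adjusted p = 0.0215, adjusted p = 0.725 with an estimated correlation), with cpHsc70-2 (Mapoly0110s0006.1) at 0.78 ± 0.11 and an HSP20-like chaperone (Mapoly0051s0013.1) at 0.62 ± 0.10. The abscisic acid and dehydration list was higher (median 0.07, which turned to -0.003 under median centring, where that of all genes was -0.074, camera adjusted p = 0.0358, adjusted p = 0.725 with an estimated correlation). Without its 78 members of other kinds its median was 0.14, with 0 of 80 called also adjusted over the list alone (camera adjusted p = 0.00357, adjusted p = 0.685 with an estimated correlation).

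With the replicate block the phenylpropanoid list (adjusted p = 0.0227, against 0.101 without it) and the glutathione transferases (0.0499 against 0.0678) also passed. With an estimated correlation and no block, adjusted p = 0.744 and 0.709. Adjusted over the list alone, 1 phenylpropanoid gene model was higher, the dirigent-like protein named above, 2 glutathione transferases were higher and 1 lower, 1 sugar transport gene was higher and 1 bHLH factor (Mapoly0037s0007.1) was lower. The AP2/ERF list without members of other kinds had 1 higher and 1 lower of 6 adjusted over the list alone (median 0.35), and did not pass as a set (camera adjusted p = 0.236). Without systemic replicate 1 the adjusted p was 0.924 for aquaporins, 0.115 for abscisic acid and dehydration as fixed, 0.0971 for ribosomal proteins and 0.0929 for heat shock proteins, and without systemic replicate 2 it was 0.104 for shikimate, 0.0705 for abscisic acid and dehydration as fixed and 0.0684 for heat shock proteins.

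The comparison of both responses asked whether changes at a distance follow those at the wound. Across 11595 genes, which are not independent replicates, mean local and systemic log2 ratios correlated at r = 0.420. Simulated unchanged groups that share the intact RNA gave 0.353 (0.300 to 0.416), so the observed value lay just above the highest of 100 simulations. The covariance was 0.0818 against a simulated 0.0188 (0.0159 to 0.0239), and the share of gene models with the same sign was 61.5% against a simulated 61.3%. Array pairs that share neither intact RNA nor dye orientation correlated at 0.192 and 0.311 (mean 0.251), above the highest simulated mean of 0.0578, and under median centring that mean was 0.156. Without systemic replicate 1 the correlation of means was 0.266. Replicate arrays of the local comparison correlated at 0.808 and those of the systemic comparison at 0.224, which was 0.137 without the filter and 0.0174 under median centring. An overlap of calls could not be given, since 0 gene models were called in systemic tissue.

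**Figure D3:**
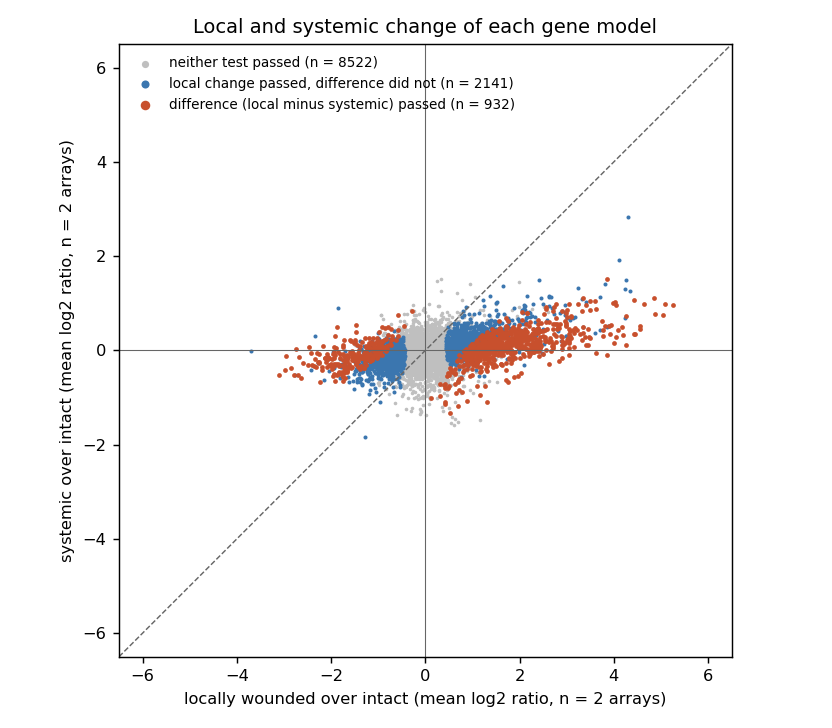
Mean log2 ratio over intact plants of each tested gene model in locally wounded tissue (x axis) and systemic tissue (y axis), with 932 gene models whose difference passed the test marked apart from 2141 called in wounded tissue without a called difference. Ratios spread far more along the local axis, and the correlation across genes was 0.420.

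The difference between both responses was tested directly. As sets, WRKY, NAC and AP2/ERF factors, heat shock proteins and glutathione transferases had higher ratios at the wound than in undamaged lobes, and peroxidases had lower ones, while MYB (camera adjusted p = 0.153) and bHLH factors (0.491) did not pass. With an estimated correlation 0 lists passed for the difference (lowest adjusted p = 0.274). By fry 7 did, 5 of them among the 14 that passed camera. WRKY factors (fry adjusted p = 0.0551) and heat shock proteins (0.101) did not pass by fry. The difference passed for 932 gene models, 680 with a higher and 252 with a lower ratio at the wound, and for 626 and 210 of them it was at least 2-fold. Of these, 916 were also called in locally wounded tissue with the same sign, and 16 were not. The difference in log2 ratio was 4.29 for both Rap2.6L (Mapoly0166s0010.1, systemic 0.75 ± 0.12) and VEP1 (Mapoly0190s0002.3, systemic 0.96 ± 0.10), with adjusted p-values of 0.00697 and 0.00501. A protein kinase (Mapoly0060s0068.1) had a local ratio of 4.26 ± 0.46 and a systemic ratio of 0.12 ± 0.46, a difference of 4.14. BAG6 (Mapoly0035s0113.1, systemic 0.44 ± 0.16) differed by 4.10, the second VEP1 model (Mapoly0190s0002.1, systemic 0.99 ± 0.08) by 4.09, HSP17.6A (Mapoly0010s0142.1, systemic 0.35 ± 0.23) by 4.08 and ECA3 (Mapoly0040s0031.1, systemic 0.52 ± 0.04) by 4.02. An alpha/beta-hydrolase (Mapoly0086s0084.1) stood at 3.86 ± 0.04 locally and -0.09 ± 0.12 in systemic tissue, a difference of 3.95.

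On the lower side, 5 of the 8 named gene models were peroxidases. Mapoly0182s0023.1 differed by -2.77 with a systemic ratio of 0.03 ± 0.26, Mapoly0332s0001.1 by -2.56 with -0.13 ± 0.26, and Mapoly0196s0012.1, where the signal in wounded tissue was not well above background, by -2.57 with -0.42 ± 0.13. Mapoly0182s0024.1 had ratios of -2.46 ± 0.08 and 0.07 ± 0.04, a difference of -2.53, and Mapoly0417s0001.1 ratios of -2.43 ± 0.06 and -0.06 ± 0.25, a difference of -2.38. The rhamnogalacturonate lyase Mapoly0026s0014.1 differed by -2.58 with a systemic ratio of -0.52 ± 0.02. An aspartyl protease (Mapoly0185s0031.1) had ratios of -2.60 ± 0.23 and -0.26 ± 0.35, a difference of -2.34, and its signal was not well above background in wounded tissue. Its bound, 6.07-fold lower there than in intact tissue, matches the local ratio and leaves no margin. S-adenosylmethionine decarboxylase (Mapoly0102s0030.1), an enzyme of polyamine synthesis, stood at -1.87 ± 1.01 and 0.49 ± 0.21, a difference of -2.36 (adjusted p = 0.0455). Without systemic replicate 2 the adjusted p was 0.0582 for Mapoly0332s0001.1, 0.0567 for Mapoly0185s0031.1 and 0.173 for Mapoly0102s0030.1, and without systemic replicate 1 it was 0.118 for Mapoly0102s0030.1. The differences of other genes named for local changes did not all pass, with 3.08 for CYP90A1 (Mapoly0033s0061.1, systemic 1.25 ± 0.89, adjusted p = 0.0715), -3.68 for CAX2 (Mapoly0030s0112.1, systemic -0.02 ± 0.30, adjusted p = 0.141) and -2.23 for the germin-like protein (Mapoly0032s0077.1, systemic -0.52 ± 0.11, adjusted p = 0.23). OPR1 (Mapoly0097s0082.1, systemic 1.10 ± 1.04) differed by 3.74 (adjusted p = 0.0359), and the SOS5 matches Mapoly0027s0081.1 and Mapoly0027s0084.1 (systemic -0.52 ± 0.30 and -0.52 ± 0.22) by -2.26 and -2.18.

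Among gene lists the peroxidases again stood out, with 51 of 136 lower at the wound than in systemic tissue and 2 higher, against 80 and 3 adjusted over the list alone (median difference -0.78, camera adjusted p = 3.66e-17, adjusted p = 0.274 with an estimated correlation). For glutathione transferases 12 of 27 were higher and 0 lower, against 15 and 0 adjusted over the list alone (0.81, camera adjusted p = 3.18e-07, adjusted p = 0.541 with an estimated correlation), and GSTF10 (Mapoly1812s0001.1) differed by 3.53. WRKY factors had 7 higher and 0 lower of 12, against 11 and 0 adjusted over the list alone (1.38, camera adjusted p = 3.18e-07, adjusted p = 0.709 with an estimated correlation), and WRKY35 (Mapoly0051s0057.1), at -0.47 ± 0.02 in systemic tissue, differed by 2.51. Heat shock proteins had 15 higher and 0 lower of 74, against 25 and 0 adjusted over the list alone (0.40, camera adjusted p = 1.21e-05, adjusted p = 0.710 with an estimated correlation). The cell wall list had 15 lower and 5 higher of 105, against 30 and 5 adjusted over the list alone (-0.42, camera adjusted p = 2.15e-06, adjusted p = 0.709 with an estimated correlation), with XTH16 (Mapoly0089s0005.1) at -1.61. Photosynthesis genes shifted lower as a set (-0.37, camera adjusted p = 1.1e-05, adjusted p = 0.710 with an estimated correlation) with 1 lower and 2 higher gene models of 134, against 0 and 1 adjusted over the list alone. With the replicate block 12 of them were lower and 2 higher. Oxylipin synthesis had 4 higher and 0 lower of 23, also adjusted over the list alone (0.79, camera adjusted p = 0.00262, adjusted p = 0.709 with an estimated correlation), with ACX2 (Mapoly0014s0189.1) at 1.52. The oil body list had 7 higher and 0 lower of 19, also adjusted over the list alone (0.57, camera adjusted p = 0.00345, adjusted p = 0.709 with an estimated correlation), with ABCG14 (Mapoly0097s0053.1) at 3.76. Leaving out systemic replicate 1 or 2 gave adjusted p-values of 0.0749 and 0.0745 for ACX2 (Mapoly0014s0189.1) and of 0.0539 and 0.0709 for XTH16 (Mapoly0089s0005.1).

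A further 6 lists also passed. NAC factors had 3 higher and 0 lower of 7, against 4 and 0 adjusted over the list alone (0.80, camera adjusted p = 0.0186, adjusted p = 0.709 with an estimated correlation), and the AP2/ERF list 4 higher and 0 lower of 15, against 6 and 0 adjusted over the list alone (0.25, camera adjusted p = 0.0338, adjusted p = 0.709 with an estimated correlation). Without the 9 proteins of other kinds, 4 of 6 AP2/ERF factors were higher and 0 lower, against 5 and 0 adjusted over the list alone (1.75, camera adjusted p = 0.000556, adjusted p = 0.656 with an estimated correlation). Phenylpropanoid genes had 8 higher and 1 lower of 82, against 12 and 3 adjusted over the list alone (0.39, camera adjusted p = 0.0358, adjusted p = 0.725 with an estimated correlation), with HCT (Mapoly0003s0198.1) at 2.66. The abscisic acid and dehydration list had 17 higher and 2 lower of 158, against 28 and 3 adjusted over the list alone (0.27, camera adjusted p = 0.0439, adjusted p = 0.725 with an estimated correlation), with ERD10 (Mapoly0056s0073.1) at 3.04. Without its 78 members of other kinds 14 of 80 were higher and 0 lower, against 25 and 2 adjusted over the list alone (0.74, camera adjusted p = 5.37e-05, adjusted p = 0.656 with an estimated correlation). The aquaporin list did not pass as fixed (camera adjusted p = 0.0549) but was lower without its 5 members of other kinds (-0.35, camera adjusted p = 0.00393, adjusted p = 0.656 with an estimated correlation), with 0 of 26 called by limma, also adjusted over the list alone, and without systemic replicate 2 its adjusted p was 0.0952. Proteasome and autophagy genes had 1 higher and 0 lower of 37, against 4 and 0 adjusted over the list alone (0.26, which turned to -0.03 under median centring, where that of all genes was -0.16, camera adjusted p = 0.0158, adjusted p = 0.710 with an estimated correlation). Chlorophyll synthesis had 0 called members of 10 by limma, also adjusted over the list alone, and a lower median (-0.46, camera adjusted p = 0.0158, adjusted p = 0.710 with an estimated correlation). Without locally wounded replicate 1 the adjusted p was 0.0853 for phenylpropanoids, 0.0720 for chlorophyll and 0.0765 for the proteasome list, and without locally wounded replicate 2 it was 0.458 for abscisic acid. Without systemic replicate 1 that of abscisic acid was 0.0718, and without systemic replicate 2 it was 0.134 for phenylpropanoids and 0.0666 for chlorophyll.

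The count of differences moved with the scaling and with the array left out. When an array is left out, the residual spread comes only from the 2 arrays of the other comparison. Such counts thus do not show which tissue's values the differences rest on. With the replicate block 1706 gene models differed. Without systemic replicates 1 and 2 in turn 164 and 113 differed, without locally wounded replicates 1 and 2 there were 581 and 928, and median centring, which moved the median of all genes to -0.16, called 19 (17 higher and 2 lower), while the scanner software's own ratio gave 467 higher and 284 lower. Of the 85 named gene models with a called difference 38 kept the call without systemic replicate 1 and 35 without systemic replicate 2.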

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

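The AP2/ERF value without other proteins was chosen after the results were seen, and the other tests before. The test of local against systemic ratios set apart 932 gene models, a count that fell to 164 and 113 without systemic replicates 1 and 2 and to 19 under median centring. Local ratios exceeded systemic ones by 4.29 for Rap2.6L (Mapoly0166s0010.1) and 4.29 for VEP1 (Mapoly0190s0002.3), by 4.14 for a protein kinase (Mapoly0060s0068.1), by 4.10 for BAG6 (Mapoly0035s0113.1), by 4.09 for the second VEP1 model (Mapoly0190s0002.1), by 4.08 for HSP17.6A (Mapoly0010s0142.1), by 4.02 for ECA3 (Mapoly0040s0031.1) and by 3.95 for an alpha/beta-hydrolase (Mapoly0086s0084.1). The difference was -2.77 for Mapoly0182s0023.1, -2.56 for Mapoly0332s0001.1, -2.53 for Mapoly0182s0024.1 and -2.38 for Mapoly0417s0001.1, all peroxidases. It was -2.58 for the rhamnogalacturonate lyase Mapoly0026s0014.1 and -2.36 for S-adenosylmethionine decarboxylase (Mapoly0102s0030.1). The peroxidase Mapoly0196s0012.1 (-2.57) and the aspartyl protease Mapoly0185s0031.1 (-2.34) were not well above background in wounded tissue, so the size of their difference is not measured exactly.

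The same test by gene list set apart 14 lists by camera with a preset correlation, of which 5 also passed by fry, and 0 with an estimated correlation. Median differences were positive for WRKY factors (1.38), glutathione transferases (0.811), NAC factors (0.801), oxylipin synthesis (0.786), oil body markers (0.568), heat shock proteins (0.403), phenylpropanoids (0.388), abscisic acid and dehydration (0.274), the proteasome (0.258, negative under median centring, as was that of all genes) and the AP2/ERF list (0.25, or 1.75 without the 9 of its 15 members that are other proteins). They were negative for peroxidases (-0.776), chlorophyll synthesis (-0.457), the cell wall (-0.419) and photosynthesis (-0.372).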

How the results depend on the processing

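The 4 lists without members of other kinds, the correlations without single arrays and the carry-over test under other settings were chosen after the results were seen. Local calls numbered 3057 and lay between 2504 and 4217 under 12 alternatives. Median centring gave 1047, every probe on its own 5347 and an added 2-fold minimum 1329, while leaving out an array gave 1536 to 2504. For median centring the cause was not tested. Testing probes raises the number of tests, and a fold minimum removes small changes by construction. Systemic tissue gave 0 calls under every alternative run, with 153 to 1549 gene models at an unadjusted p under 0.05. The difference gave 932, with the replicate block 1706, every probe on its own 1657, median centring 19, and 113 to 928 without single arrays, where fewer arrays were fitted. The gene list shifts numbered 38, with 36 to 39 without single arrays, 18 by fry and 0 by camera with an estimated correlation (lowest adjusted p 0.274). The other settings gave 35 to 39. The correlation of both responses was 0.420, the cross pairs 0.251, and 0.266 to 0.404 without single arrays. Under median centring the cross pairs gave 0.156 and the systemic replicates 0.0174, against 0.224. After carry-over was taken off, r between systemic arrays was 0.141 (0.0573 to 0.143 in 5 other settings and -0.0581 under median centring), and mean r with local ratios was 0.1315 (0.101 to 0.134, and 0.0581 under median centring, where a fitted share was negative). Of 108 named local calls 93 kept theirs without locally wounded replicate 1, 102 without replicate 2 and 79 under median centring, and at least 105 in the other settings run, but for all 8 channels above background, where 97 could be tested and kept it. Of 85 named differences 61 kept theirs with the scanner software's ratio and 13 under median centring, and the adjusted p of Rap2.6L (Mapoly0166s0010.1) was 0.0585 with the scanner's ratio. CAX2 (Mapoly0030s0112.1) lost its local call without the filter (adjusted p = 0.0517), as did the germin-like protein Mapoly0032s0077.1 (0.0632).

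Lists lost a call in some settings. Local adjusted p-values were 0.0810 for shikimate, 0.0581 for MYB and 0.135 for proteasome under median centring, 0.230 for AP2/ERF, 0.0600 for NAC and 0.169 for MYB with all 8 channels above background, 0.0515 for NAC with a normexp offset of 16, and 0.0506 and 0.132 for MYB with the scanner's ratio and without the filter. Systemic values were 0.0810 for ribosomal proteins under median centring and 0.0536 for abscisic acid without the filter. Those of the difference were 0.0525 for AP2/ERF with the scanner's ratio, 0.211 for it with all 8 channels, 0.0856 for phenylpropanoids without the filter and 0.172 for proteasome under median centring. The replicate block changed no set call of a list but those given in the report. It raised many counts of called members. Local photosynthesis had 54 lower and 9 higher with it, against 27 and 7, and local cytochrome P450 34 lower and 20 higher, against 18 and 15. In the difference, phenylpropanoids had 25 higher and 4 lower, against 8 and 1. Aquantile left every ratio as it was by construction, a slide block was not possible with 1 slide, and the difference cannot be fitted on the arrays of a single comparison. In the runs that leave a tissue with a single array, that array is assumed to vary like the others. Median spot signal was 77.0 to 129 against a background of 36 to 45. In signals with known changes added to the systemic arrays, 0 of 67 genes raised 1.5-fold, 6 of 67 raised 2-fold and 44 of 66 raised 4-fold were called, with 2 other genes. Where so few genes changed, systemic changes of up to 2-fold were thus mostly not detectable, and some of 4-fold were missed. These signals do not show what would be called if many genes had changed. In the local comparison 3057 gene models were called, and 926 higher and 403 lower ones changed at least 2-fold, so many calls were of smaller changes.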

Other observations

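The sets of gene models with a common description, and the tests of the shared direction of both responses, were chosen after the results were seen. Sets of at least 5 tested gene models with the same Arabidopsis description numbered 265, and camera with a preset correlation passed 22 locally, 11 in systemic tissue and 15 in the difference, while with an estimated correlation none passed (adjusted p = 0.997). In locally wounded tissue 6 of 8 models of the putative late embryogenesis abundant (LEA) set, proteins that protect cells during drying, rose and 0 fell (median 2.66, adjusted p = 0.00257). Of the other LEA sets, the family set of 20 had 10 higher and 0 lower (median 1.48, adjusted p = 0.00855, and 0.273 with a median of 0.55 without locally wounded replicate 2), the domain set of 8 had 6 and 0 (1.62, 0.0392, and 0.0672 with the replicate block and 0.0675 without locally wounded replicate 2), and the hydroxyproline-rich set of 12 did not pass (0.290). Of 20 heavy metal transport and detoxification proteins 10 rose and 0 fell (median 0.64, adjusted p = 0.0261), and of 27 cupredoxins, small copper proteins, 11 fell and 1 rose (median -0.40, adjusted p = 0.00171). Fasciclin-like proteins had 5 lower and 0 higher of 8 (median -0.85, adjusted p = 0.00975), and sodium/calcium exchangers 6 lower and 0 higher of 7 (median -0.85, adjusted p = 0.0109). Among 21 cupins 10 rose and 2 fell (median 0.86, adjusted p = 0.0231), and without locally wounded replicate 1 their adjusted p was 0.162.

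In systemic tissue 0 members of these sets were called by limma. The putative LEA set had a median of 0.66 (adjusted p = 0.00294) and passed in every scaling, with the replicate block and without each array, always with the preset correlation. Gene models of that description include 4 loci with consecutive identifiers (Mapoly0119s0007.1 to Mapoly0119s0010.1, systemic median 0.85). Common stretches of their probes were not examined for this set, and the preset correlation of 0.01 treats members as nearly independent. The other LEA sets did not pass (0.0667 for the family set, 0.0571 for the domain set and 0.412 for the hydroxyproline-rich set). Chalcone and stilbene synthases, which start flavonoid synthesis, had a median of 0.64 over 18 models (adjusted p = 0.00758), PAL1 matches 0.79 over 6 (0.0117), chlorophyll a/b binding proteins 0.49 over 24 (0.00257) and proton pumps matched to AHA11 -0.34 over 12 (0.00128). Without systemic replicate 1 these 4 sets had adjusted p-values of 0.279, 0.303, 0.869 and 0.238, so they rest on that array.

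Systemic and local ratios correlated across genes, though the share with the same sign (61.5%) lay within that of simulated unchanged groups (60.4% to 62.7%), and the replicate 2 arrays correlated at 0.321, below the simulated mean of 0.348. Intact RNA common to same-numbered arrays would leave no correlation in cross pairs of arrays, which had r = 0.2512 (0.156 under median centring), and dye bias would give those pairs a negative covariance, which was 0.06386. Wounded RNA carried over as a single share (fitted at 1.88% and 3.43% on genes at least 8-fold up) would leave no correlation with local ratios in the other genes, but a mean r of 0.1315 was left, and 0.101 to 0.134 in 5 other settings, above the highest shuffled (0.0409) and simulated (0.0578) values, which argues against it as the whole cause. Median centring cannot test this, since the systemic arrays correlated at 0.0174 there before any share was taken off and the fitted shares were -0.143% and 6.06%, and 2 earlier tests of carry-over did not decide: systemic medians of genes that fell at least 4-fold (-0.112 and -0.286 against predicted -0.0222 and -0.0391), and the r of 0.141 left between the systemic arrays, which need not be the part that resembles local ratios. A smaller carry-over, or a share that differs between genes, and a response of undamaged lobes to wounding stay open.

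Class III peroxidases fell together in wounded tissue. Near-identical copies measured by the same probes would leave little in members without a common stretch of 20 bases. These 88 gene models had a median of -0.7102 (quartiles -1.43 and -0.0932), and 45 of them fell and 8 rose. The 89 members that fell lay in 58 groups of linked probes, so probes with common stretches did not make the whole decrease. Probes were compared only with each other and not with the transcripts of other members, so cross-hybridisation at other positions stays open. The lowest median of 10000 sets matched on signal was -0.1703 against -1.0, so the list fell relative to other genes of like signal. A general loss of abundant transcripts would lower other genes alike. These sets cannot show such a loss, since loess centres the ratios near 0 at each signal level. The list kept its direction under every scaling run. A lower share of a tissue or cell type rich in peroxidases could also give this and was not tested, so a coordinated decrease is a hypothesis.

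Loci with consecutive identifier numbers tended to change alike at the wound. Their log2 ratios correlated at r = 0.2304 over 6233 pairs (Spearman 0.161), above the highest of 100000 shuffles (0.0528, permutation p = 1e-05, the smallest they can give). Cross-hybridisation of near-identical copies would leave no correlation among pairs with different Arabidopsis matches and no common stretch. Over 4062 such pairs r was 0.09432 (highest shuffled 0.0685). Matches counted as different when gene and description differed, so a pair could still belong to the same gene family. Probes were not compared with the transcript of the neighbour, so cross-hybridisation at other positions stays open. The other pairs, with a common match or stretch or without a match, had r = 0.381. Runs of at least 4 called loci with the same sign numbered 14, against a mean of 1.5 and at most 9 in shuffles, while the longest run, 8 loci, was also reached in shuffles, and the 14 runs included LEA proteins (Mapoly0035s0082.1 to Mapoly0035s0089.1, median 2.93, 1 of 8 without a description), chalcone synthases with phenylalanine ammonia-lyases (Mapoly0070s0067.1 to Mapoly0070s0072.1, median 2.12) and peroxidases (Mapoly0196s0010.1 to Mapoly0196s0017.1, median -1.80, 2 of 8 without a description), and these runs were chosen after their values were seen. Tandem gene clusters or neighbouring genes under common control may account for this, but identifiers stand in for genome order here and were not checked against a genome.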
